A study of Mus musculus with 27 samples.

How the data were processed

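Poly-A RNA of the ileum, cecum and colon was sequenced by the submitters from male C57BL/6 mice on control feed or on feed with arsenic, with 4 or 5 libraries per region and diet. The deposited table holds raw counts of reads per Ensembl gene, 1 column per library, for 52550 genes in 27 libraries (13 control, 14 arsenic), all of which were used. The submitters' processing notes name HISAT2 2.1.0, SAMtools without a version, HTSeq 0.6.0 and DESeq2 1.6.3. The genome build, the annotation release and the strand setting were not given in the sources used here, so counts of antisense and overlapping genes are uncertain. Counts of near-identical genes, such as the defensins, Hspa1a and Hspa1b, and genes with processed copies, such as those of ribosomal proteins, are uncertain too. Gene symbols were joined by Ensembl identifier for 52403 genes, and the 147 without a match held 0.00312 to 0.0059% of the counts of a library.

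Each library held 15717600 to 18208518 counts. Pearson correlations of log2 CPM (after adding 1) between libraries of a group were 0.9794 to 0.9973, and the common biological coefficient of variation was 0.243 in the ileum, 0.130 in the cecum and 0.245 in the colon. The test used R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, libraries were scaled with TMM over the genes kept, and robust quasi-likelihood F-tests compared the diets within each region and the regions within the control mice, the latter in a fit of the 13 control libraries. The arsenic effect averaged over regions used limma 3.58.1 voom with replicate number as a random effect through duplicateCorrelation (statmod 1.5.0), which gave a correlation of 0.093. The difference of the arsenic effect between regions was an edgeR F-test of the interaction. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison.

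For the lists, 48 sets of genes for pathways, cell types and regional markers were fixed before the data were examined, and lists with at least 5 genes tested were compared with limma camera at a preset correlation of 0.01. The alternatives were camera with an estimated correlation, limma fry and an exact permutation test of the mean log2 CPM of each list over the 126 splits of 9 libraries, with a prior count of 2. Counts adjusted over the list alone repeat the Benjamini-Hochberg correction within the members of a list.

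Genes are named by a rule fixed at the same time. It takes the 10 largest changes in each direction among called genes with a mean of at least 1 CPM (10 CPM between regions) and groups that did not overlap, or, for the averaged effect, the same sign in each region. It adds the 3 members of each called list with the smallest p in the direction of the list, 10 genes of arsenic handling and oxidative stress in every diet comparison, and the 10 smallest p-values of the interaction. Predicted genes, pseudogenes and receptor segments are left out of the rule. Some genes that the rule selects are not reported here.

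The procedure was tested on simulated data with 2-fold and 4-fold changes put into counts like those of each comparison. It recovered 57.7% and 84% of changes in the ileum, 84% and 96.9% in the cecum, 61.2% and 89.5% in the colon, 65% and 90.7% for cecum against ileum, 59.2% and 88% for colon against cecum, 43.4% and 76.8% for the interaction and 90.7% and 95.9% for the averaged effect. False calls made up 2.88%, 7.77%, 4.61%, 4.97%, 5.19%, 5.56% and 3.7% of calls in the same order. For lists, 2 of 2 lists shifted 1.5-fold in simulated cecum data were recovered by each of the 3 tests, with 0 other lists called. The simulated genes varied independently, so this run cannot tell how often lists are called by chance where genes vary together. Among splits of the real libraries, 90 of 100 in the ileum, 14 of 100 in the cecum and 100 of 100 in the colon called as many lists.

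The alternatives tried were RLE and upper-quartile scaling, DESeq2 1.42.0, limma voom with sample quality weights, no filter and a stricter filter of 1 CPM, all 27 libraries in 1 fit, list scores as covariates, a block for the replicate number, each library left out in turn, and, chosen after the data were seen, scores of clock genes and of position as covariates, a linear model of the heat shock list score on diet and clock score, and sets of libraries left out. Figures were drawn with matplotlib 3.10.9.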

Results

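RNA was sequenced from the ileum, the cecum and the colon of male C57BL/6 mice that ate a control feed or a feed holding arsenic at 30 ug/g for 60 days. Sodium arsenite made up 72.7% of the added arsenic, the methylated form DMA 19.0%, sodium arsenate 7.3% and the methylated form MMA 1.0%. The 27 libraries formed 6 groups: ileum control (n = 4), ileum arsenic (n = 5), cecum control (n = 4), cecum arsenic (n = 5), colon control (n = 5) and colon arsenic (n = 4). Libraries held 15717600 to 18208518 counted reads, a range too narrow for depth to separate the groups. Levels are scaled counts (CPM) given as mean ± SD over the libraries of a group, and log2 fold changes are given ± SE. P-values measure the spread between libraries, since the labels number the libraries of each region without stating that equal numbers came from the same mouse.

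The first comparison asked how arsenic feed altered the ileum, the last part of the small intestine. Mt1 (ENSMUSG00000031765), a metallothionein that binds metal ions, rose from 39.8 ± 4.01 CPM (n = 4) to 164.5 ± 57.5 CPM (n = 5), a log2 change of 2.05 ± 0.24 (edgeR adjusted p = 0.00357). Genes of cholesterol synthesis rose, led by Mvk and Mvd of the mevalonate pathway. Heat shock genes fell, among them Hspa1b, an inducible HSP70, from 18.2 ± 3.13 to 6.91 ± 0.70 CPM. Its partner Hsph1 fell from 115 ± 15 to 40.25 ± 7.35 CPM. In all, 1190 of 16305 genes passed the edgeR quasi-likelihood test, 656 higher and 534 lower on arsenic. Of these, 57 of the higher and 143 of the lower genes changed more than 2-fold.

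Of the 26 cholesterol synthesis genes tested in the ileum, 13 rose and 0 fell, against 21 higher and 1 lower when adjusted over the list alone. Mvk changed by 1.54 ± 0.18, Mvd by 1.45 ± 0.23 and Insig1, a sterol-regulated brake on the pathway, by 1.20 ± 0.14 on the log2 scale (edgeR adjusted p = 0.00357, 0.0106 and 0.00357). The list median was 0.71. limma camera called it higher with a preset correlation (adjusted p = 3.1e-11), with adjusted p = 0.78 with an estimated correlation. Of 24 heat shock genes, 8 fell and 0 rose, against 13 lower when adjusted over the list alone. Their median was -0.39 (limma camera adjusted p = 0.00000171, and adjusted p = 0.39 with an estimated correlation). Hsph1 changed by -1.51 ± 0.14, Hspa1b by -1.40 ± 0.14 and Chordc1, a co-chaperone of HSP90, by -1.16 ± 0.09 (edgeR adjusted p = 0.0023, 0.0023 and 0.00133). In the unfolded protein and integrated stress response list, 7 of 32 genes fell, also 7 when adjusted over the list alone. Hspa5, the main chaperone of the endoplasmic reticulum, changed by -0.88 ± 0.12 and Dnajc3 by -0.52 ± 0.10 (edgeR adjusted p = 0.00559 and 0.0142, the latter 0.0596 and 0.073 without control 2 and 3). Its limma camera adjusted p was 0.000348, and adjusted p = 0.78 with an estimated correlation.

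Paneth cells secrete antimicrobial defensins at the base of the ileal crypts. Of 18 Paneth cell genes, 2 fell over all genes tested and 16 were lower when adjusted over the list alone. The list median was -0.89 (limma camera adjusted p = 0.000000906, and adjusted p = 0.94 with an estimated correlation). The defensin genes Defa26 and Defa3 changed by -0.92 ± 0.23 and -0.83 ± 0.22 (edgeR adjusted p = 0.038 and 0.0458). Neither call was stable. Defa26 had edgeR adjusted p = 0.101, 0.0807, 0.128, 0.0743, 0.073 and 0.0587 without control 1, 2, 3 and 5 and arsenic 13 and 14. Defa3 had edgeR adjusted p = 0.121, 0.0564, 0.149 and 0.0834 without the same controls and 0.0848, 0.0831, 0.0704 and 0.0744 without arsenic 12, 13, 14 and 15. Their near-identical sequences leave the split of reads between defensins uncertain. Itln1, an intelectin, stood at 971.5 ± 390 CPM on arsenic and 1873 ± 486 CPM on control feed and did not pass (edgeR adjusted p = 0.0828). The list score of mean log2 CPM was 7.01 ± 0.56 on arsenic and 7.89 ± 0.34 on control feed. Fabp6, a bile acid binding protein of the distal ileum chosen after its values were seen, held 6.13 and 1.33 CPM in arsenic 14 and 15, while the other 7 ileum libraries held 218 to 4270 CPM.

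Among the other lists called in the ileum by limma camera, nuclear oxidative phosphorylation was higher (5 of 39 genes rose and 0 fell, 11 when adjusted over the list alone; Uqcrc1 0.86 ± 0.19). Ribosomal proteins were higher too (6 of 42 genes, 7 when adjusted over the list alone; Rplp2 0.81 ± 0.13). Fatty acid oxidation and PPARA targets were also called higher, with 5 of 32 genes up and 2 down (9 and 4 when adjusted over the list alone). The beta-oxidation genes Acaa2 and Acads changed by 0.71 ± 0.11 and 0.83 ± 0.16. The limma camera adjusted p of these 3 lists was 0.0000288, 0.000348 and 0.0133, and each had adjusted p = 0.99 with an estimated correlation. Fatty acid oxidation had limma camera adjusted p = 0.129 without arsenic 15. Without control 2 the genes Uqcrc1, Acads and Rplp2 had edgeR adjusted p = 0.0978, 0.0696 and 0.0522, and their calls were lost in 5, 2 and 1 of 9 such fits. Smooth muscle genes were called lower as a list (median -0.43, limma camera adjusted p = 0.000235, and adjusted p = 0.99 with an estimated correlation). Of 18 members 0 passed the edgeR test over all genes (13 at an unadjusted p under 0.05) and 5 passed when adjusted over the list alone. Acta2, an actin of smooth muscle, stood at 748.9 ± 68.1 CPM on arsenic and 1168 ± 330 CPM on control feed. Lists for Reg3 and antimicrobial lectins, small intestine regional markers, intestinal stem cells and goblet cells were called lower (limma camera adjusted p = 0.0193, 0.0243, 0.0426 and 0.0443) with 0 members passing the edgeR test in either count (8, 6, 2 and 5 at an unadjusted p under 0.05). With an estimated correlation these 4 lists had adjusted p = 0.79, 0.99, 0.99 and 0.99. Regional markers had limma camera adjusted p = 0.111, 0.0505 and 0.0647 without arsenic 11, 13 and 14. Stem cells had 0.117, 0.0768, 0.222 and 0.0742 and goblet cells 0.171, 0.0594, 0.19 and 0.0618 without control 3, control 5, arsenic 12 and arsenic 15, and goblet cells 0.142 without arsenic 14. With the clock covariate the oxidative phosphorylation and goblet cell lists turned direction (limma camera adjusted p = 0.48 for both). In all, limma camera with an estimated correlation called 0 of 47 ileum lists (2 at an unadjusted p under 0.05), while limma fry called 4.

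Beyond the lists, the largest rises in the ileum included Acot1, a thioesterase of fatty acid metabolism (log2 1.68 ± 0.32), and Efna3, an ephrin (1.65 ± 0.26). Others were Gramd2 (1.40 ± 0.21), Dclk3 (1.33 ± 0.32) and Bri3bp (1.29 ± 0.29). The largest falls were in Mroh6 (-2.33 ± 0.41), Tcp10a (-2.33 ± 0.42), Slc6a18, an amino acid transporter (-2.26 ± 0.58), and Zbtb16, a zinc finger transcription factor (-2.22 ± 0.42). Plb1, a phospholipase of the brush border, fell from 743.2 ± 61.9 to 176.8 ± 100 CPM. Nlrp9b, an inflammasome sensor of the gut epithelium, fell from 126.1 ± 22.9 to 33.6 ± 10.9 CPM. Without control 2 each of 9 named calls was lost: edgeR adjusted p was 0.128 for Slc6a18, 0.108 for Dclk3, 0.104 for Bri3bp, 0.0705 for Zbtb16, 0.0668 for Acot1, 0.0596 for Tcp10a, 0.0553 for Mroh6, 0.0541 for Plb1 and 0.0522 for Efna3. Slc6a18, Bri3bp, Dclk3 and Acot1 lost the call in 7, 6, 5 and 3 of 9 such fits. Slc10a6, Gpr17, Fam151a and Alpk1 fell by 1.89, 1.84, 1.79 and 1.75 on the log2 scale. Of the genes fixed for arsenic handling and oxidative stress, none but Mt1 passed. The arsenic methyltransferase gene As3mt stood at 65.9 ± 10.7 on arsenic and 51.6 ± 3.98 CPM on control feed (edgeR adjusted p = 0.102). Gsto1 stood at 381.1 ± 83.2 and 264.4 ± 7.31 CPM (edgeR adjusted p = 0.0674). Abcc2 stood at 237.3 ± 153 and 298.0 ± 39.3 CPM and Aqp3 at 18.5 ± 15.4 and 15.4 ± 5.79 CPM (edgeR adjusted p = 0.627 and 0.838). The edgeR adjusted p of Hmox1, Nqo1, Gclc and Slc7a11 was 0.849, 0.173, 0.118 and 0.939. Mt2 held 0 counts in all 27 libraries and could not be tested. Leaving out 1 library moved the ileum count of 1190 to 292, 121, 243 and 751 without control 1, 2, 3 and 5 and to 639, 737 and 598 without arsenic 12, 13 and 14. It was 673 without arsenic 14 and 15 together. DESeq2 gave 2006 genes, limma voom with sample weights 2129, and all 27 libraries in 1 edgeR fit 2889. A smooth muscle covariate gave 19 and a covariate of clock gene expression 0 (1877 at an unadjusted edgeR p under 0.05).

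The second comparison asked the same question of the cecum, the pouch where the large intestine begins. Mt1 rose from 19.4 ± 1.36 (n = 4) to 63.2 ± 9.67 CPM (n = 5), a log2 fold change of 1.71 ± 0.11 (edgeR adjusted p = 0.000000841). Heat shock genes fell, with Hspa1a and Hspa1b, 2 near-identical HSP70 genes whose reads may be split between them, at -2.22 ± 0.25 and -2.16 ± 0.32. The constitutive Hspa8 fell from 1843 ± 165 to 870.4 ± 89.5 CPM. Duoxa2 and Duox2, which together form the epithelial enzyme that makes hydrogen peroxide, fell, Duoxa2 from 74.6 ± 22.2 to 11.7 ± 5.48 CPM and Duox2 from 235.9 ± 54.4 to 65.3 ± 18.8 CPM. The sodium/proton exchanger gene Slc9a3 fell from 391.9 ± 67.7 to 171.3 ± 19.0 CPM. In all, 3933 of 15590 genes passed the edgeR test, 1768 higher and 2165 lower. That split became 2448 higher and 1627 lower with upper-quartile scaling. TMM factors over all 27 libraries did not overlap between the diets in the cecum (0.8525 to 0.8837 on control feed, 0.9027 to 0.9847 on arsenic). The number of genes with a count did not overlap there either (21832 to 22130 and 22351 to 23119). Small changes in the cecum may thus depend on the scaling.

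Of 24 heat shock genes in the cecum, 17 fell and 1 rose, against 18 and 2 when adjusted over the list alone (median -0.40). Hspa8, Chordc1 and Dnaja1 changed by -1.08 ± 0.08, -0.99 ± 0.07 and -0.80 ± 0.06 (edgeR adjusted p = 0.00000184, 0.00000129 and 0.00000162). In the unfolded protein list 18 of 32 genes fell and 0 rose, 19 when adjusted over the list alone. Sdf2l1 changed by -0.70 ± 0.08, Creld2 by -0.67 ± 0.10 and Syvn1 by -0.53 ± 0.07. Of 26 cholesterol synthesis genes 17 rose and 4 fell in either count. The sterol carrier gene Stard4 changed by 0.65 ± 0.07 and Fdps by 1.73 ± 0.20, a gene at low counts here (6.71 ± 1.5 CPM on arsenic). The limma camera adjusted p of the heat shock, unfolded protein and cholesterol lists was 0.0000000327, 0.00000587 and 0.0000897, and had adjusted p = 0.16, 0.22 and 0.48 with an estimated correlation. The immediate early and dissociation list had 8 of 21 genes lower and 1 higher (9 and 1 when adjusted over the list alone). The phosphatase gene Dusp1 fell from 60.9 ± 6.32 to 26.4 ± 4.26 CPM, and Jun and Klf4 changed by -0.71 ± 0.09 and -0.43 ± 0.06. Its limma camera adjusted p was 0.00189, and adjusted p = 0.52 with an estimated correlation.

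Epithelial lists were called lower in the cecum. Of 17 enterocyte genes 6 fell and 0 rose in either count (Ceacam20 -0.52 ± 0.06, Krt18 -0.46 ± 0.08, Ceacam1 -0.40 ± 0.07). Of 27 junction genes 9 fell and 1 rose (10 and 2 when adjusted over the list alone; F11r -0.43 ± 0.05, Cdh1 -0.35 ± 0.05). Of 29 colonic ion and water transport genes 11 fell and 2 rose in either count (Slc9a3 -1.19 ± 0.12, Car4 -0.72 ± 0.10, the water channel Aqp8 -0.61 ± 0.09). Of 24 large intestine regional markers 10 fell and 0 rose (11 and 1 when adjusted over the list alone). The limma camera adjusted p of these 4 lists was 0.0017, 0.00357, 0.00476 and 0.00189, and adjusted p = 0.48, 0.48, 0.39 and 0.28 with an estimated correlation. Of 22 genes in the list named Reg3 and antimicrobial lectins 8 fell and 0 rose, 10 when adjusted over the list alone. The members named here are not Reg3 genes. Duox2 changed by -1.85 ± 0.26, Sprr1a by -1.32 ± 0.11 and the acute phase gene Saa1 by -0.45 ± 0.08. The median of that list was -0.27 while its mean was 0.06. Its limma camera adjusted p was 0.00396, and adjusted p = 0.2 with an estimated correlation. Fatty acid synthesis was called lower (6 of 20 genes fell and 2 rose, 8 and 2 when adjusted over the list alone). The lipase gene Pnpla3 changed by -1.65 ± 0.31, Me1 by -0.65 ± 0.13 and Fads2 by -0.44 ± 0.10 (limma camera adjusted p = 0.015, and adjusted p = 0.48 with an estimated correlation). In the interferon response list 6 of 44 genes fell and 4 rose in either count. Mx1 changed by -0.82 ± 0.14, Irf7 by -0.71 ± 0.12 and Ifih1 by -0.39 ± 0.10 (limma camera adjusted p = 0.0269, and adjusted p = 0.74 with an estimated correlation). The list lost its call without control 1, control 2 and arsenic 14 (limma camera adjusted p = 0.175, 0.228 and 0.104) and was called higher with the clock covariate (0.00000012). With that covariate the changes of Fads2, Irf7 and Ifih1 turned to 0.12, 0.01 and 0.14.

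Lymphocyte and stromal lists were called higher in the cecum. Of 23 T cell and innate lymphocyte genes 11 rose and 0 fell, 12 when adjusted over the list alone (median 0.61). The interleukin 7 receptor gene Il7r changed by 1.26 ± 0.35 and Trbc1 by 1.06 ± 0.25. The B cell and follicle list had a median of 2.87 with 1 of 17 genes called in either count. That gene was Ebf1 at 0.85 ± 0.18 (edgeR adjusted p = 0.00413). Cd22 stood at 12.7 ± 10.1 CPM on arsenic and 1.499 ± 1.65 CPM on control feed. Fcer2a stood at 5.598 ± 4.43 and 0.476 ± 0.685 CPM, and neither Cd22 nor Fcer2a passed (edgeR adjusted p = 0.0677 and 0.0684). The B cell score spread from 0.36 to 3.93 over the arsenic libraries and from -0.44 to 2.15 over the controls. In the MHC class II list 1 of 12 genes rose, 0 when adjusted over the list alone. H2-Oa stood at 1.63 ± 1.11 against 0.234 ± 0.213 CPM. The limma camera adjusted p of these 3 lists was 0.000195, 0.00282 and 0.0204, and adjusted p = 0.55, 0.64 and 0.64 with an estimated correlation. MHC class II had limma camera adjusted p = 0.0859, 0.0635 and 0.0557 without control 4, arsenic 12 and arsenic 14. Of 18 smooth muscle genes 5 rose (8 when adjusted over the list alone; Hspb6 0.65 ± 0.13, Cnn1 0.56 ± 0.14, Myl9 0.33 ± 0.07). Of 14 fibroblast genes 6 rose in either count (Dpt 0.45 ± 0.08, Dcn 0.42 ± 0.10, Clec3b 0.34 ± 0.09). Of 14 endothelial genes 3 rose (1 when adjusted over the list alone; Pecam1 0.59 ± 0.10). Of 28 extracellular matrix genes 8 rose and 1 fell (9 and 1 when adjusted over the list alone; Thbs1 0.52 ± 0.12, Postn 0.46 ± 0.09). The limma camera adjusted p of these 4 lists was 0.000247, 0.00423, 0.015 and 0.00471, and adjusted p = 0.64, 0.52, 0.48 and 0.64 with an estimated correlation. The endothelial list had limma camera adjusted p = 0.0612 without control 1. With the enterocyte covariate the MHC class II, extracellular matrix and smooth muscle lists turned direction without passing (limma camera adjusted p = 1, 0.72 and 0.13), and Cnn1 went to -0.00. Among genes, edgeR adjusted p was 0.0581, 0.0582 and 0.0525 for Cnn1 without control 1, 4 and 5, 0.0525 and 0.0565 for Il7r without control 2 and 5, and 0.0874, 0.0893 and 0.0661 for H2-Oa without control 2, 4 and 5.

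Ribosomal protein genes rose in the cecum, 25 of 42 and 0 lower (28 when adjusted over the list alone), by a median of 0.22. Rpl26 changed by 0.37 ± 0.06 and Rpl22 by 0.34 ± 0.06 (limma camera adjusted p = 0.0000000154, and adjusted p = 0.48 with an estimated correlation). Of 12 genes in the mitochondrial genome list 5 rose and 0 fell in either count, with mt-Cytb at 0.32 ± 0.09 (limma camera adjusted p = 0.00396, and adjusted p = 0.48 with an estimated correlation). The mitochondrial gene mt-Rnr2, outside that list, went the other way at -0.58 ± 0.12 (edgeR adjusted p = 0.00488) and was called lower in the ileum and colon too. Small intestine regional markers were called higher, with 4 of 22 genes up and 1 down in either count. Apob, the structural protein of chylomicrons, changed by 0.55 ± 0.12 (limma camera adjusted p = 0.0106, and adjusted p = 0.64 with an estimated correlation). The list lost its call without arsenic 14 (limma camera adjusted p = 0.0512), the library with the highest Paneth cell score (1.13 against at most -0.53 in the other 8 cecum libraries) and 69.9 CPM of Fabp6. With the clock covariate the list turned direction (limma camera adjusted p = 0.4), and Apob stood at -0.09. With an estimated correlation limma camera called 0 of 46 cecum lists (5 at an unadjusted p under 0.05), while limma fry called 16. The largest rises included Slamf6 (3.02 ± 0.72), Ifi213 (2.90 ± 0.75), the urea transporter gene Slc14a1 (2.86 ± 0.43) and Rab33a (2.63 ± 0.32). They also included Trim30b (2.16 ± 0.44), the T cell gene Cd5 (2.14 ± 0.61), the ion channel gene Trpv3 (2.09 ± 0.20), Zfp831 (2.02 ± 0.39) and Dnajb3 (2.00 ± 0.43, but -1.82 with the clock covariate). For Slamf6 edgeR adjusted p was 0.0515 and 0.0527 without control 2 and 4, for Cd5 0.0684, 0.0774 and 0.0557 without control 2, control 5 and arsenic 12, and for Ifi213 0.0653, 0.0711, 0.0672 and 0.061 without control 1, 2, 4 and 5. Atcayos (1.99 ± 0.35) is an antisense transcript that cannot be told from its partner because the strand setting of the counts is not given. Among the largest falls, the EGF receptor ligand gene Areg fell from 109.7 ± 18.3 to 22.4 ± 12.3 CPM and the peptide hormone gene Adm from 15.95 ± 3.85 to 3.76 ± 0.90 CPM. The stress factor gene Atf3 fell from 94.3 ± 12.2 to 31.0 ± 8.51 CPM, and Trim6 and Plk3 changed by -1.90 ± 0.29 and -1.62 ± 0.25. As3mt stood at 32.1 ± 2.55 on arsenic and 31.4 ± 3.05 CPM on control feed (edgeR adjusted p = 0.821). Gsto1, Hmox1, Nqo1, Gclc, Slc7a11 and Abcc2 did not pass (edgeR adjusted p = 0.275, 0.179, 0.392, 0.407, 0.143 and 0.286). Aqp3 was below the count filter. The count of 3933 was 2021 with all 27 libraries in 1 fit and 1669 without arsenic 11, 12 and 13, the libraries highest in B cell genes. Covariates of the smooth muscle, B cell, enterocyte and clock gene scores gave 2603, 1961, 490 and 1 (1516 at an unadjusted edgeR p under 0.05 with the clock score).

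The third comparison asked how arsenic feed altered the colon, where fewer genes passed. Heat shock genes fell, with Hsph1 going from 101.3 ± 20.0 (n = 5) to 34.6 ± 7.32 CPM (n = 4). Hspa1b fell from 108.8 ± 32.9 to 42.1 ± 1.98 CPM. For Hsph1 edgeR adjusted p was 0.0525 and 0.0543 without arsenic 13 and 15, and for Hspa1b 0.057, 0.0704, 0.0907, 0.0728 and 0.0852 without control 2 and arsenic 11, 12, 13 and 15. The cold-inducible RNA binding protein gene Cirbp rose from 28.6 ± 4.35 to 74.6 ± 6.40 CPM. Mt1 stood at 80.7 ± 30.7 on arsenic and 31.2 ± 18.2 CPM on control feed, a log2 difference of 1.37 ± 0.40 which did not pass (edgeR adjusted p = 0.166). In all, 107 of 16492 genes passed the edgeR test, 60 higher and 47 lower, of which 15 and 6 changed more than 2-fold.

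Of 24 heat shock genes in the colon 8 fell and 0 rose, 15 lower when adjusted over the list alone (median -0.39). Hsph1 changed by -1.55 ± 0.18, Chordc1 by -1.09 ± 0.11 and the co-chaperone Stip1 by -0.80 ± 0.08 (edgeR adjusted p = 0.00822, 0.00433 and 0.00433). Of 32 unfolded protein genes 4 fell and 0 rose, 12 when adjusted over the list alone. Hspa5 changed by -0.84 ± 0.12, Hyou1 by -0.80 ± 0.11 and Syvn1 by -0.56 ± 0.08 (each with edgeR adjusted p = 0.0169). These 3 lost the call without each of the 4 arsenic libraries (up to 0.0852, 0.0852 and 0.0846 without arsenic 15), and Hsph1 without arsenic 13 and 15 (0.0525 and 0.0543). Of 26 cholesterol synthesis genes 8 rose and 0 fell, 19 and 1 when adjusted over the list alone (median 0.72). Hmgcs1, which makes HMG-CoA, changed by 1.14 ± 0.18, Lss by 1.13 ± 0.20, Mvd by 0.97 ± 0.14 and Fdft1 by 0.94 ± 0.14. Their calls were lost in 7, 7, 6 and 6 of 9 fits that left out 1 library, with edgeR adjusted p up to 0.0935 and 0.14 without arsenic 11, 0.0719 without arsenic 13 and 0.084 without arsenic 15. The limma camera adjusted p of the heat shock, unfolded protein and cholesterol lists was 2.88e-16, 3.22e-10 and 1.3e-13, and adjusted p = 0.22, 0.22 and 0.28 with an estimated correlation. The immediate early and dissociation list was called lower and the smooth muscle list higher (limma camera adjusted p = 0.0134 and 0.0246, each with adjusted p = 0.99 with an estimated correlation). Of their 22 and 18 members 0 passed the edgeR test in either count (6 and 0 at an unadjusted p under 0.05). The immediate early list had limma camera adjusted p = 0.146 without control 3, and the smooth muscle list 0.169, 0.0918 and 0.409 without control 1, control 4 and arsenic 11. With an estimated correlation limma camera called 0 of 48 colon lists (3 at an unadjusted p under 0.05), while limma fry called 3. Fos stood at 95.6 ± 18.5 on arsenic and 207.3 ± 76.9 CPM on control feed, and Synpo2 of smooth muscle at 316.3 ± 58.6 and 252.1 ± 45.7 CPM.

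Other rises in the colon were Atcayos (2.15 ± 0.33), the retinal G protein receptor gene Gpr179 (1.61 ± 0.29), Zc3h6 (1.40 ± 0.21), Hoga1 (1.06 ± 0.20) and Krba1 (1.01 ± 0.10). Other falls were Banp, a chromatin protein (-1.69 ± 0.14), the clock output gene Nfil3 (-1.53 ± 0.23), Tra2a, a splicing factor (-1.09 ± 0.14), Rfx2 (-0.98 ± 0.18), Dnaja1 (-0.98 ± 0.13), Ttll3 (-0.92 ± 0.11) and Zbtb40 (-0.91 ± 0.15). Of 9 fits that left out 1 library, Gpr179 and Hoga1 lost the call in 8, Zc3h6, Nfil3, Rfx2 and Zbtb40 in 7, Atcayos in 6, Dnaja1 and Ttll3 in 4 and Tra2a in 2. The highest edgeR adjusted p was 0.152, 0.0907, 0.124 and 0.061 for Gpr179, Zc3h6, Zbtb40 and Tra2a without arsenic 12 and 0.152 for Hoga1 without arsenic 11. Without arsenic 15 it was 0.102, 0.166, 0.102, 0.069 and 0.0613 for Nfil3, Rfx2, Atcayos, Dnaja1 and Ttll3. As3mt stood at 29.2 ± 3.75 and 28.8 ± 1.09 CPM (edgeR adjusted p = 0.949). Gsto1, Abcc2, Hmox1, Nqo1, Gclc and Slc7a11 did not pass (edgeR adjusted p = 0.961, 0.235, 0.734, 0.864, 0.627 and 0.867). Pancreatic acinar genes stood high in control 2 and 3 and arsenic 11, where Ctrb1 held 202, 174 and 47.0 CPM against at most 1.30 CPM in the other 6 colon libraries. The distal Hox gene Hoxb13 ranged from 0 CPM in control 1 to 239 CPM in control 3, and both genes were chosen after their values were seen. The count of 107 became 351, 33, 36, 36 and 61 without control 1, 2, 3, 4 and 5, and 12, 12, 6 and 10 without arsenic 11, 12, 13 and 15. DESeq2 gave 592 genes, limma voom with sample weights 609 and all 27 libraries in 1 fit 493. edgeR with smooth muscle, B cell, Hox position and clock covariates gave 32, 398, 1164 and 0 (600 at an unadjusted p under 0.05), and edgeR gave 0 without the 3 libraries high in pancreatic genes (1275 at an unadjusted p under 0.05).

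**Figure D1:**
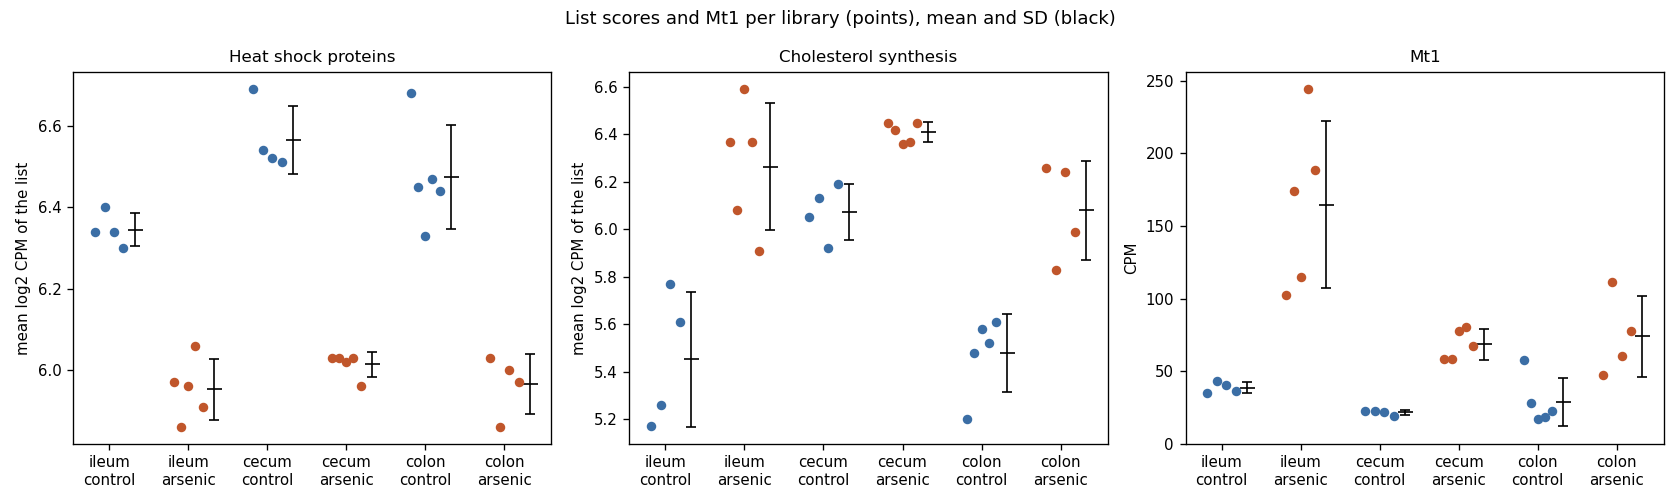
Mean log2 CPM of the heat shock and cholesterol synthesis lists and CPM of Mt1 in each of the 27 libraries (points; blue control, orange arsenic), by region and diet, with group mean and SD in black. Heat shock scores were 6.30 to 6.69 in the controls and 5.86 to 6.06 on arsenic, and cholesterol scores were higher on arsenic within each region.

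A further comparison asked which changes the regions shared and where they differed. Of all genes tested, 22 were called higher and 21 lower in each of the 3 regions, and those named here were chosen after the values were seen. The higher genes held several of cholesterol metabolism (among them Aacs, Fdft1, Hmgcs1, Hsd17b7, Lss, Mvd and Mvk). They also held Cirbp, at 1.15 ± 0.14 in the ileum, 1.34 ± 0.13 in the cecum and 1.38 ± 0.12 in the colon. The lower genes held chaperones and their partners (Cacybp, Chordc1, Dnaja1, Hsp90aa1, Hspa1b, Hspa4l, Hspa8, Hspa13, Hsph1) and genes of the endoplasmic reticulum (Hspa5, Creld2, Syvn1). Banp changed by -1.66 ± 0.16, -1.49 ± 0.13 and -1.69 ± 0.14. Ileum and cecum calls shared 105 higher and 156 lower genes, against 74.0 and 70.5 for independent lists. They shared 92 with opposite signs against 148.4. Ileum and colon shared 23 higher and 23 lower genes (2.463 and 1.535 for independent lists), and cecum and colon 51 and 44 (6.68 and 6.60), with 0 of opposite sign in both pairs.

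**Figure D2:**
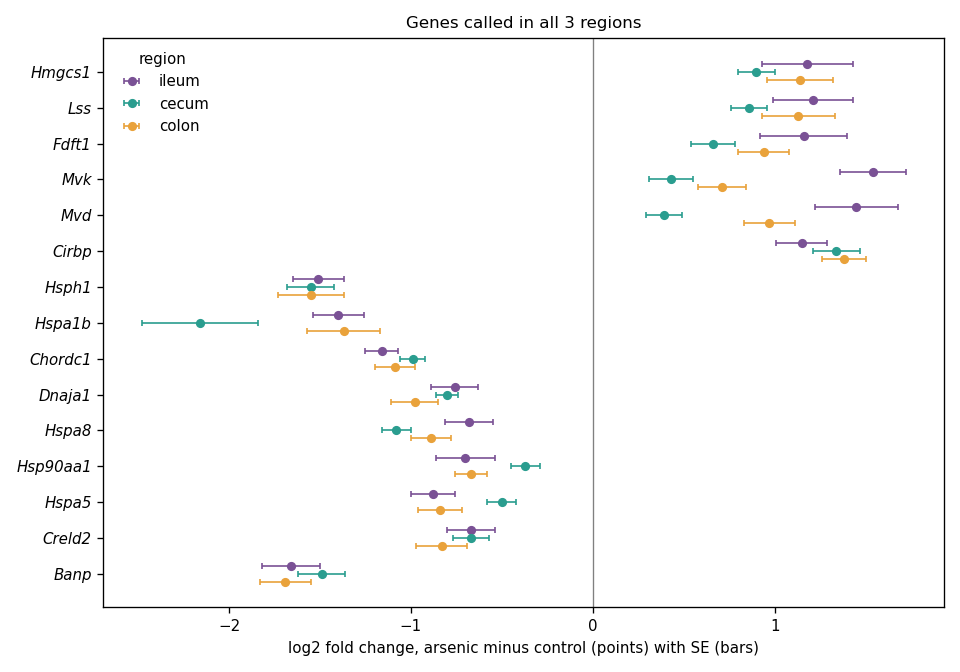
Log2 fold change, arsenic minus control, with SE for 15 genes called in the ileum, cecum and colon. Cholesterol genes and Cirbp lie above 0 and chaperone genes and Banp below 0 in each region, with Hspa1b lowest in the cecum at -2.16 ± 0.32.

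Averaged over the 3 regions in a limma voom fit, 2878 of 17763 genes passed, 1337 higher and 1541 lower. Of these, 2503 had the same sign in each region. Mt1 was higher by 1.72 ± 0.18, Atcayos by 1.69 ± 0.21 and Fdps by 1.65 ± 0.24 (limma adjusted p = 0.000000636, 0.00000607 and 0.0000339). Cirbp was higher by 1.30 ± 0.08 and Zc3h6 by 1.25 ± 0.13 (limma adjusted p = 3.44e-11 and 0.000000258). The clock output genes Dbp and Ciart rose by 1.20 ± 0.19 and 1.10 ± 0.16, and Slc14a1 and Ms4a18 by 1.40 ± 0.33 and 1.37 ± 0.42. The largest average falls were in Zbtb16 (-1.89 ± 0.29), Duoxa2 (-1.77 ± 0.30), Pnpla3 (-1.68 ± 0.54), Banp (-1.61 ± 0.09), Hspa1b (-1.59 ± 0.15) and Hsph1 (-1.54 ± 0.10). Next came the MAP kinase phosphatase gene Dusp6 (-1.34 ± 0.22), Sgk1, a kinase induced by glucocorticoids (-1.33 ± 0.23), Plb1 (-1.33 ± 0.37) and Areg (-1.32 ± 0.27). Plb1 had limma adjusted p = 0.0548 without number 2, Ms4a18 0.0569, 0.0532, 0.0541 and 0.0859 without 1, 2, 3 and 12, and Pnpla3 0.0795, 0.0705, 0.0708, 0.0511 and 0.115 without 1, 2, 5, 11 and 13. The fixed genes As3mt, Gsto1, Abcc2, Aqp3, Hmox1, Nqo1, Gclc and Slc7a11 did not pass (limma adjusted p = 0.206, 0.463, 0.551, 0.931, 0.757, 0.313, 0.701 and 0.982).

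The arsenic effect differed between regions for 1353 of 17763 genes in an edgeR test of the interaction. For 1227 of these genes the estimated effects did not all have the same sign among the regions. Signs were counted whether or not the effect passed in a region, so this count does not show that arsenic acted in opposite directions. Bcorl1, a partner of transcriptional repressors, rose by 0.86 ± 0.16 in the ileum and stood at -0.81 ± 0.22 in the colon (edgeR adjusted p of the difference = 0.0000132). In the cecum it fell from 31.88 ± 3.81 to 10.54 ± 1.15 CPM. Dhcr7, the last enzyme of cholesterol synthesis, rose by 1.20 ± 0.20 in the ileum and changed by -0.32 ± 0.06 in the cecum (edgeR adjusted p of the difference = 0.0000701). The chromatin remodeller gene Chd4 changed by 0.95 ± 0.11 and -0.25 ± 0.08 (edgeR adjusted p of the difference = 0.0000878). Kremen1, a receptor of Dickkopf proteins that inhibits Wnt signalling, changed by 0.73 ± 0.12 and -0.27 ± 0.08, Trip10 by 0.35 ± 0.07 and -0.49 ± 0.06, Tmem63b by 0.64 ± 0.11 and -0.17 ± 0.06 in the same regions. Pigs at 0.94 ± 0.12 and Zfp950 at -1.26 ± 0.13 passed in the ileum, and Ube2h at -0.63 ± 0.06 and Sympk at -0.45 ± 0.06 passed in the cecum. The interaction count was 269 without the libraries numbered 2 and 495 without those numbered 13.

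**Figure D3:**
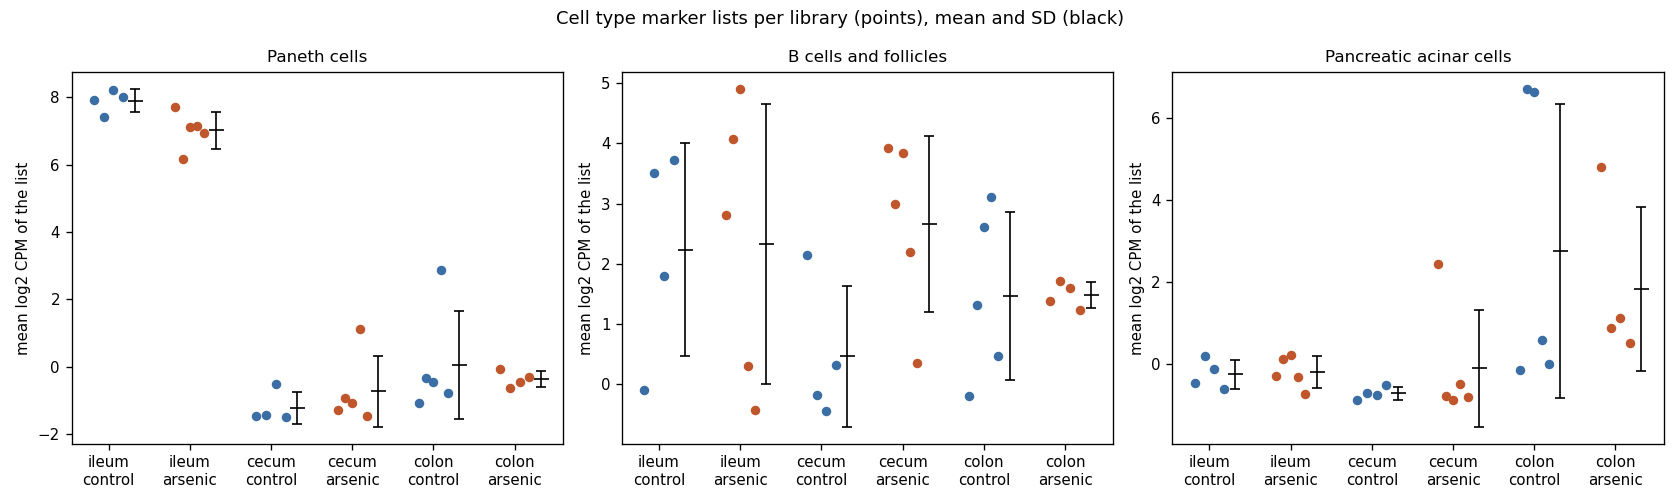
Mean log2 CPM of the Paneth cell, B cell and pancreatic acinar lists in each of the 27 libraries (points; blue control, orange arsenic), by region and diet, with group mean and SD in black. Paneth scores in the ileum were 7.42 to 8.23 on control feed and 6.16 to 7.70 on arsenic, and pancreatic scores reached 6.69 in colon control libraries and 4.80 in colon arsenic 11.

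The control mice also gave a comparison of regions without arsenic, first of the cecum (n = 4) against the ileum (n = 4). Genes of nutrient absorption stood lower in the cecum, with the intestinal sugar transporter Slc5a1 at 80.7 ± 4.99 against 2627 ± 446 CPM. The brush border peptidase Dpp4 stood at 21.25 ± 1.62 against 1235 ± 88.8 CPM and Apob at 275.9 ± 44.0 against 3604 ± 634 CPM. Genes of the large intestine stood higher, with the carbonic anhydrase Car1 at 30440 ± 3470 against 5.96 ± 11.4 CPM and Aqp8 at 3437 ± 311 against 0.694 ± 1.31 CPM. In all, 9266 of 16882 genes passed the edgeR test, 4800 higher and 4466 lower in the cecum. Of these, 4379 differed more than 2-fold. The balance of directions turned with RLE scaling (4499 higher and 4795 lower), with DESeq2 (4743 and 5108) and in arsenic-fed mice (4258 and 4620). It also turned without a filter and with the stricter filter, but not with the replicate block (4591 and 4246).

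limma camera called 20 of 48 lists between cecum and ileum controls, 7 higher and 13 lower. Of these 0 held with an estimated correlation (5 at an unadjusted p under 0.05, and 35 called by limma fry). For the 13 lower lists that test gave adjusted p = 0.087 (sugar and peptide digestion) to 0.72. Of 31 genes of sugar and peptide digestion 30 were lower in the cecum and 0 higher in either count (Mgam -3.88 ± 0.11). Of 25 lipid absorption genes 22 were lower and 2 higher in either count (Acsl5 -3.55 ± 0.13, Dgat1 -3.33 ± 0.15). All 18 Paneth cell genes were lower in either count, with Pla2g2a at 0.065 ± 0.051 against 34.6 ± 8.78 CPM. Habp2 stood at 0.031 ± 0.063 against 18.8 ± 7.51 CPM and Defa3 at 0.017 ± 0.035 against 36.5 ± 10.0 CPM. Among the largest differences, Defa21, Defa22 and Defa20 stood at 1818 ± 445, 1665 ± 429 and 707.3 ± 180 CPM and the pentraxin Mptx2 at 394 ± 169 CPM in the ileum, and each below 0.2 CPM in the cecum. Defa2, Defa32, Defa36, Defa23, Mmp7 and Defa37 had 0 counts in the cecum controls and were at least 6150-fold, 5040-fold, 1960-fold, 1470-fold, 1510-fold and 1210-fold lower there, against a floor of 3 counts over the group. Small intestine regional markers held 26 of 30 lower and 1 higher in either count. T cell genes were lower (21 of 24 and 0 higher in either count; Cd5 -3.03 ± 0.37, Itgae -2.53 ± 0.26, Il7r -2.23 ± 0.26). MHC class II was lower (7 of 12 lower and 1 higher in either count; H2-Aa -3.80 ± 0.35, Ciita -3.21 ± 0.29, H2-Eb1 -2.94 ± 0.30). Adipocyte (11 of 14 and 1 in either count; Aqp7 -4.65 ± 0.57, Retn -3.01 ± 0.56, Adrb3 -3.00 ± 0.54) and enteroendocrine genes were lower (9 of 17 and 1 in either count; Cck -3.09 ± 0.34, Scg2 -1.39 ± 0.19). Gip stood at 0.016 ± 0.032 against 22 ± 11.8 CPM. Smooth muscle genes were lower (14 of 18, 16 when adjusted over the list alone; Hspb6 -2.00 ± 0.19, Mylk -1.50 ± 0.16, Pgm5 -1.37 ± 0.18). Fibroblast (7 of 14; Grem1 -3.01 ± 0.45, Lum -1.52 ± 0.20, Dcn -1.24 ± 0.18) and extracellular matrix genes were lower (12 of 31 lower and 2 higher; Tgfbi -3.42 ± 0.17). Unfolded protein (20 of 32 lower and 7 higher; Trib3 -3.88 ± 0.28, Creld2 -1.15 ± 0.14, Hspa5 -1.07 ± 0.11) and ribosomal protein genes were lower (23 of 42; Rpl10 -0.59 ± 0.10, Rps24 -0.58 ± 0.11, Rps19 -0.50 ± 0.10). The counts of these last 4 lists were equal when adjusted over the list alone. The fibroblast list had limma camera adjusted p = 0.0649 without ileum control 1.

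Lists higher in the cecum controls included colonic ion and water transport (20 of 31 higher and 6 lower; Car2 7.11 ± 0.25, Slc16a1 3.74 ± 0.15, Slc9a2 2.18 ± 0.10) and large intestine regional markers (17 of 28 and 3; Hao2 8.87 ± 0.56, Sult1a1 4.90 ± 0.29). With an estimated correlation the 7 higher lists had limma camera adjusted p = 0.44 to 0.72. Junctions (18 of 27 and 3; Cldn23 2.69 ± 0.19, Jup 1.26 ± 0.09, Crb3 1.18 ± 0.09) and fatty acid oxidation were higher as well (18 of 32 and 8; Slc25a20 2.42 ± 0.11, Cpt1a 2.01 ± 0.16, Acadl 1.31 ± 0.10). Nuclear oxidative phosphorylation (22 of 39 and 3; Cox6a1 1.02 ± 0.12, Uqcrfs1 0.94 ± 0.08, Cox5a 0.91 ± 0.10) and cholesterol synthesis (16 of 26 and 1; Dhcr7 2.13 ± 0.16, Nsdhl 1.21 ± 0.12, Srebf2 1.18 ± 0.14) were higher too. Adjusted over the list alone, the higher and lower counts of these 6 lists were 20 and 6, 17 and 3, 18 and 3, 19 and 8, 23 and 3, and 16 and 2. Hox genes, which mark position along the gut, had 18 of 29 higher and 5 lower (21 and 5 when adjusted over the list alone). Their list had limma camera adjusted p = 0.0528 and 0.0596 without ileum control 3 and 5. Hoxa9 stood at 82.6 ± 4.69 against 0.101 ± 0.077 CPM and Hoxa7 at 3.06 ± 0.25 on the log2 scale. Hoxa10 and Hoxa11 were at least 1410-fold and 55.3-fold higher than ileum groups with 0 counts. The largest rises beyond the lists were Cyp2d34, Abca12, Gal3st2c, Fa2h, Slc6a14, Slc37a2 and Pbp2, at 204.9 ± 46.7, 390.1 ± 39.6, 1250 ± 220, 619.5 ± 21.7, 644.9 ± 58.4, 2111 ± 195 and 20.9 ± 9.22 CPM in the cecum and below 2 CPM in the ileum.

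The colon controls (n = 5) were then set against the cecum controls (n = 4). Muc2, the main mucin of goblet cells, stood at 6130 ± 1430 in the colon and 1417 ± 82.2 CPM in the cecum. The smooth muscle filament gene Des was 2.80-fold higher and the neuronal gene Uchl1 4.04-fold higher in the colon, while the cell cycle gene Rrm2 changed by -2.19 ± 0.18 on the log2 scale. In all, 7970 of 16882 genes passed the edgeR test, 3704 higher and 4266 lower in the colon. Of these, 2283 of the higher and 711 of the lower genes differed more than 2-fold. The balance of directions turned with RLE scaling (3895 higher and 3728 lower), with DESeq2 (4191 and 3890) and in arsenic-fed mice (3825 and 2751). It did not turn with the replicate block, without a filter or with the stricter filter.

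Muscle, nerve and stromal lists were higher in the colon: all 18 smooth muscle genes (Des 1.49 ± 0.22, Synpo2 1.26 ± 0.19, Lmod1 1.12 ± 0.15), and all 18 genes of enteric neurons and glia (Uchl1 2.02 ± 0.19, Snap25 1.77 ± 0.21, Stmn2 1.55 ± 0.15) in either count. limma camera called 11 lists higher and 8 lower of 48 between colon and cecum controls. Of these 0 held with an estimated correlation (5 at an unadjusted p under 0.05, and 23 called by limma fry), with adjusted p = 0.34 to 0.73 for the 11 higher lists. Of 31 extracellular matrix genes 25 were higher and 1 lower (27 and 2 when adjusted over the list alone; Tgfbi 1.66 ± 0.16, Col4a2 1.42 ± 0.13, Col4a1 1.41 ± 0.14). Of 14 endothelial genes 13 were higher in either count (Tie1 1.61 ± 0.24, Egfl7 1.42 ± 0.22, Plvap 1.04 ± 0.11). Of 14 fibroblast genes 11 were higher (12 when adjusted over the list alone; Lum 1.65 ± 0.19, Dpt 1.00 ± 0.14, Pdgfra 0.89 ± 0.15). Goblet cell genes were higher (13 of 16 higher and 2 lower in either count; Ccl6 2.48 ± 0.17, Muc2 2.11 ± 0.15, Agr2 1.82 ± 0.14). Enteroendocrine genes were higher (10 of 17 and 1, 11 and 1 when adjusted over the list alone; Pyy 1.96 ± 0.17, Scg2 1.96 ± 0.19, Scg5 1.54 ± 0.19), as were tuft cell genes (6 of 12, 8 when adjusted over the list alone; Dclk1 1.47 ± 0.17, Rgs13 1.32 ± 0.24, Trpm5 0.95 ± 0.21). MHC class II had 5 of 12 higher in either count (H2-Aa 1.34 ± 0.31, Ciita 1.24 ± 0.28, H2-Eb1 1.14 ± 0.27). The MHC class II list had limma camera adjusted p = 0.0556 without cecum control 4. In arsenic-fed mice it turned direction (limma camera adjusted p = 0.57) and Ciita stood at -0.09. Clock genes had 10 of 21 higher and 3 lower (11 and 3 when adjusted over the list alone; Dbp 1.41 ± 0.20, Rora 0.85 ± 0.15), and the list had limma camera adjusted p = 0.0662, 0.0777, 0.0868 and 0.0737 without cecum control 1 and 2 and colon control 3 and 4. All 7 pancreatic acinar genes tested were higher in either count, with Clps at 24.6 ± 21.8 against 0.113 ± 0.108 CPM, and Zg16 of that list, also a goblet cell gene, at 1.08 ± 0.19. Among the colon controls Ctrb1 held 202 and 174 CPM in control 2 and 3 and at most 0.216 CPM in the others, so its difference rests on those libraries. The pancreatic list score was 6.69 in the highest colon control and -0.14 in the lowest. That list had limma camera adjusted p = 0.0561, 0.0627 and 0.0556 without cecum control 1, 2 and 4.

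Metabolic and proliferation lists were called lower in the colon by limma camera. With an estimated correlation these 8 lists had adjusted p = 0.39 to 0.63, and 0 passed. Of 39 nuclear oxidative phosphorylation genes 33 were lower and 1 higher in either count (Uqcrfs1 -0.94 ± 0.07, Sdhc -0.67 ± 0.08). Of 36 cell cycle genes 28 were lower (30 when adjusted over the list alone; Birc5 -1.03 ± 0.14, Tk1 -0.84 ± 0.11). Of 32 fatty acid oxidation genes 23 were lower and 1 higher (25 and 1 when adjusted over the list alone; Slc27a2 -4.30 ± 0.38, Hadha -1.05 ± 0.11, Etfdh -0.75 ± 0.07). Of 26 cholesterol synthesis genes 17 were lower in either count (Nsdhl -0.99 ± 0.12, Sc5d -0.68 ± 0.09). Of 39 NRF2 and glutathione genes 24 were lower and 3 higher (25 and 3 when adjusted over the list alone; Gstm3 -1.94 ± 0.17, Gclc -1.84 ± 0.15, Gstm4 -1.35 ± 0.14). Of 41 xenobiotic genes 17 were lower and 6 higher (18 and 7 when adjusted over the list alone; Sult1d1 -1.38 ± 0.15, Ces2c -0.88 ± 0.10, Cyp3a13 -0.74 ± 0.08). Of 18 enterocyte genes 13 were lower and 1 higher in either count (Krt20 -1.07 ± 0.12, Vil1 -0.86 ± 0.09, Cdhr2 -0.83 ± 0.09). Of 25 arsenic methylation and transport genes 10 were lower and 3 higher in either count (Pnp2 -1.79 ± 0.11, Ahcy -1.66 ± 0.15, Slc2a1 -1.23 ± 0.11). The last of these lists had limma camera adjusted p = 0.0703, 0.0559 and 0.0504 without cecum control 4, cecum control 5 and colon control 2. Large single differences with wide spread over the colon controls were Tgm3 (1225 ± 1120 CPM), Mptx1 (2222 ± 2410), Atp12a (437.8 ± 426) and Ang4 (562.2 ± 532). The same held for Lpo (25.5 ± 22.8), Insl5 (24.3 ± 22.4), Nxpe4 (115.8 ± 89.7), B3gnt7 (150.9 ± 138) and the trypsin inhibitor gene Spink1 (96.85 ± 72.1). Of these 9 genes Ang4 was the highest in the cecum, at 4.14 ± 1.88 CPM. Slc26a1, St3gal5, Epop, Mpp6, Mal, Vsig2, Sprr1a and Gal3st2c were lower in the colon by 6.32, 5.18, 4.86, 4.23, 4.37, 3.87, 3.95 and 5.69 on the log2 scale.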

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

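All tests that weigh explanations in this part were chosen after the results they test had been seen. The predictions for the splits were written after the results too, while the test of outlying libraries and the interaction were planned.

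The arsenic effect differed between regions for 1353 genes by the edgeR interaction test, and the 10 with the smallest adjusted p were Bcorl1 (0.0000132), Dhcr7 (0.0000701), Chd4 (0.0000878), Kremen1 (0.0000878), Pigs (0.000112), Ube2h (0.000117), Trip10 (0.000126), Sympk (0.000208), Tmem63b (0.000208) and Zfp950 (0.000208). The smooth muscle list was called lower in the ileum and higher in the cecum and colon (limma camera adjusted p of the difference = 0.000000164 and 0.000000435, and adjusted p = 0.96 and 0.99 with an estimated correlation). In the colon 0 of its 18 members passed the edgeR test (0 at an unadjusted p under 0.05). The colon call was lost without control 1, control 4 and arsenic 11 (limma camera adjusted p = 0.169, 0.0918 and 0.409), and the cecum direction turned with the enterocyte covariate (0.13). Small intestine regional markers were called lower in the ileum and higher in the cecum (limma camera adjusted p of the difference = 0.00942, and adjusted p = 0.96 with an estimated correlation). These calls were lost without ileum arsenic 11, 13 and 14 (limma camera adjusted p = 0.111, 0.0505 and 0.0647) and without cecum arsenic 14 (0.0512). Chance was an unlikely source of the interaction count, where the real split gave 1353 genes and the highest of the others 574. Of 100 splits 1, the real one, gave a count as large.

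In 14 cases 1 library lay far from the others of its group by the Dixon test, over 198 groups of values, where chance alone marks about 1 in 20 groups, or 9.9. The Paneth cell list score stood apart in cecum control 4 (-0.53), cecum arsenic 14 (1.13) and colon control 4 (2.88), and the pancreatic acinar list in cecum arsenic 11 (2.43) and colon arsenic 11 (4.80). The tuft cell list stood apart in cecum control 5 (1.5) and the list of neutrophils, mast cells and eosinophils in cecum arsenic 14 (-0.07). On the log2 CPM scale, Abcc2 stood apart in cecum control 4 (2.27) and colon control 4 (3.51), Aqp3 in colon arsenic 11 (-0.08), and Hmox1 and Slc7a11 in colon arsenic 12 (2.83 and 0.21). The most counted gene took 2.241% of ileum arsenic 11 and 2.586% of colon arsenic 11.

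Heat shock genes were lower on arsenic in all 3 regions, with no overlap of the diets in any region (smallest exact permutation p these splits can give, 0.0079, in each). Adjusted over the lists, the exact permutation p was 0.12 in the ileum, 0.052 in the cecum and 0.13 in the colon. Since 8 lists would have to tie at the smallest p for 1 to pass, and 3, 7 and 3 did, these adjusted values decide nothing about the list. Clock gene scores, centred within each region and averaged by replicate number, were higher on arsenic by 1.25, while in the ileum control 1 (0.57) lay above arsenic 13 (0.53). A clock covariate cannot decide whether a different clock phase was the whole cause. Clock scores did not overlap between the diets in the cecum or the colon, and in the ileum only through control 1 and arsenic 13. With the clock score as a covariate the list medians were -0.43, -0.46 and -0.45 against -0.39, -0.40 and -0.39 without it (limma camera adjusted p = 0.00013, 0.0001 and 2.7e-10, and adjusted p = 0.85, 0.47 and 0.54 with an estimated correlation), while edgeR gene counts of 1190, 3933 and 107 became 0, 1 and 0 (1877, 1516 and 600 at an unadjusted p under 0.05). Of 24 members 0 passed the edgeR test with that covariate in each region (6, 10 and 9 at an unadjusted p under 0.05). In a linear model the list score still differed between the diets by -0.35 ± 0.08, -0.37 ± 0.11 and -0.40 ± 0.14. It no longer passed without ileum arsenic 13 (-0.27), cecum control 5 and arsenic 11 (-0.38 and -0.32), and colon control 2, 4 and 5 and arsenic 13 (-0.34, -0.39, -0.40 and -0.37). A different clock phase, for part or all of the fall, and a time of collection that acts apart from these clock genes stay open, because the labels give no time. A lower tissue temperature may contribute, since the cold-inducible gene Rbm3 rose by 0.43 ± 0.08 on average (limma adjusted p = 0.00068). Handling at dissection stays open. The immediate early list had medians of -0.27 in the ileum, -0.26 in the cecum and -0.28 in the colon (limma camera adjusted p = 0.323, 0.00189 and 0.0134, and adjusted p = 0.99, 0.52 and 0.99 with an estimated correlation). In the cecum 8 of 21 members fell, and the colon call was lost without control 3 (limma camera adjusted p = 0.146). The diet itself stays open as a biological difference that was not tested apart from these.

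The Paneth cell list was called lower in the ileum on arsenic, with a median of -0.89 and 2 of 18 members passing over all genes (limma camera adjusted p = 0.000000906, and adjusted p = 0.94 with an estimated correlation). Tables argue against different positions of the pieces as the whole cause, since the median was -0.75 with a position score as a covariate. A larger share of muscle would raise smooth muscle genes, and the 18 members of that list all lay below 0 (median -0.43, limma camera adjusted p = 0.000235, and adjusted p = 0.99 with an estimated correlation). Of these 18, 0 passed the edgeR test over all genes (13 at an unadjusted p under 0.05), so a fall of muscle is not claimed, but its scores of 7.30 to 7.47 on arsenic against 7.30 to 8.15 on control feed hold no rise. Reads shared between defensins are argued against by the members that are not defensins, with a median of -0.95. The exact permutation p of the list score was 0.032, and 0.21 when adjusted over the lists. The fall may be biological, as a hypothesis only.

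Lymphocyte and stromal lists were called higher in the cecum on arsenic by limma camera. Of these lists 0 passed with an estimated correlation (adjusted p = 0.55 for T cells, 0.64 for B cells and 0.48 to 0.64 for the 4 stromal lists), and 1 of 17 B cell members was called. For the B cell genes a smaller share of epithelium is argued against as the whole cause. The lower quartile of B cell members (1.36) lay above the upper quartile of enteric neuron and glia members (0.34). T cell members were not compared in this way, so a smaller share of epithelium stays open for them. Lymphoid follicles in some pieces could account for the T cell genes, whose median went from 0.61 to 0.27 with the B cell score as a covariate. For stroma a smaller share of epithelium stays open. The largest median of the 4 lists was 0.11 with the enterocyte score as a covariate. That score nearly separated the diets in the cecum (9.39 to 9.60 on arsenic, 9.58 to 9.74 on control feed). A fall with this covariate therefore cannot tell epithelium from the diet itself. Follicles are argued against as the whole cause of the stromal rise, since 4 of 4 lists were still called with the B cell score. The smooth muscle median went from 0.37 to 0.18 with that score (limma camera adjusted p = 0.032), so part of its rise stays open to follicles, and the medians of the other 3 lists did not fall (0.26 to 0.38, 0.38 to 0.44 and 0.19 to 0.27). The diet stays open for each of these, as it was not tested apart.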

How the results depend on the processing

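The clock, enterocyte and position covariates, the exact permutation tests of lists and the sets of libraries left out were tests chosen after the data were seen. Over all alternatives, named genes gave 6654 values, of which 5973 kept direction and side of the threshold, 614 lost the call, 60 gained it and 7 changed sign. Lists gave 1074 values, of which 882 kept theirs, 184 lost the call and 8 changed direction. Clock scores overlapped between the diets in the ileum alone, so calls lost, turned or kept with that covariate decide nothing about their cause. With it limma camera still called the heat shock list in all 3 regions (adjusted p = 0.00013, 0.0001 and 2.7e-10), with adjusted p = 0.85, 0.47 and 0.54 with an estimated correlation. In each region 0 of its members passed the edgeR test with that covariate.

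The ileum count of 1190 was 2006 with DESeq2, 2129 with limma voom weights, 2889 with all 27 libraries, 19 with the smooth muscle covariate, 0 with the clock covariate (edgeR, 1877 at an unadjusted p under 0.05) and 673 without arsenic 14 and 15, where fewer libraries were compared. The cecum count of 3933 was 2021 with all 27 libraries, 2603, 1961, 490 and 1 with the smooth muscle, B cell, enterocyte and clock covariates, and 1669 without arsenic 11, 12 and 13. The colon count of 107 was 592 with DESeq2, 609 with limma voom weights, 493 with all 27 libraries, 32, 398, 1164 and 0 with the smooth muscle, B cell, position and clock covariates (600 at an unadjusted edgeR p under 0.05), and 0 without control 2, control 3 and arsenic 11 (1275 at an unadjusted edgeR p under 0.05). Except where fewer libraries were compared, the cause was not tested. Leaving out 1 library gave 121 (without control 2) to 1583 (without arsenic 15) genes in the ileum, 3070 to 4313 in the cecum, 6 (without arsenic 13) to 351 (without control 1) in the colon, 1956 to 3158 averaged, 269 (without 2) to 1500 for the interaction, 8442 to 8806 for cecum against ileum and 6853 to 8931 for colon against cecum.

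With an estimated correlation limma camera called 0 lists in each of the 5 comparisons (2, 5, 3, 5 and 5 at an unadjusted p under 0.05), and the exact permutation test 0 in each of the 3 diet comparisons (7, 18 and 4 at an unadjusted p under 0.05). In the ileum, 12 lists became 4 with limma fry and 19 with the clock covariate, and 10 to 15 when 1 library was left out. In the cecum, 21 became 12 with the enterocyte covariate and 19 to 25 when 1 library was left out. In the colon, 5 became 16 with the smooth muscle covariate, 3 with limma fry, 8 with the clock and 9 with the position covariate, and 4 (without control 3) to 12 (without control 1), with 8 without arsenic 11 and 9 without arsenic 13. Cecum against ileum gave 13 lists in arsenic-fed mice, not 20, and 20 to 23 when 1 library was left out, and colon against cecum 16 to 22. The cause was not tested.

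The sign of the estimate changed in the cecum for Cnn1 (-0.00, enterocyte covariate) and, with the clock covariate, for Fads2 (0.12), Irf7 (0.01), Apob (-0.09), Ifih1 (0.14) and Dnajb3 (-1.82). In colon against cecum it changed for Ciita (-0.09) in arsenic-fed mice. The values of Cnn1 and Irf7 lay at about 0. List directions changed, with their limma camera adjusted p, for ileum oxidative phosphorylation and goblet cells (0.48 and 0.48, clock covariate), cecum interferon response and small intestine regional markers (0.00000012 and 0.4, clock covariate), cecum MHC class II, extracellular matrix and smooth muscle (1, 0.72 and 0.13, enterocyte covariate) and MHC class II in colon against cecum (0.57, arsenic-fed mice). Of these only the cecum interferon response list was called in its new direction. The cause was not tested.

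A block for the replicate number gave 1287 interaction genes, 8837 genes and 24 lists for cecum against ileum, and 7751 genes and 22 lists for colon against cecum. Of 24 pairs of libraries with equal numbers, 13 had a correlation of residuals above 0.1 (-0.11 to 0.25, median 0.115 against -0.03 for other pairs) and the other 11 did not, so the numbers were not read as pairing. As a hint from the data alone, 13 of the 24 were the best match of their first library. The averaged fit used the number as a random effect, and the clock scores, centred within each region, were averaged by number. The diets shared no replicate numbers, so no block could be fitted within a region.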

Other observations

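The circadian clock list of 21 genes fixed beforehand, which mixes genes of opposite phase, was not called for arsenic in the ileum, cecum or colon (limma camera adjusted p = 0.98, 0.172 and 0.721). A group of 15 clock genes, chosen and divided after its values were seen, moved in part with arsenic averaged over the regions. Of 10 targets of the clock activators 6 rose in the limma fit, among them Dbp (1.20 ± 0.19), Ciart (1.10 ± 0.16) and Bhlhe41 (0.99 ± 0.19), while Per1, Per2, Nr1d1 and Nr1d2 did not pass. Of 5 other clock genes 5 fell, the activators Arntl (-0.89 ± 0.18), Npas2 (-0.60 ± 0.14) and Clock (-0.34 ± 0.06), with Cry1 (-0.75 ± 0.12) and Nfil3 (-1.11 ± 0.18). The labels give no time of collection. The clock score difference was 0.99 in the ileum, 1.61 in the cecum and 1.16 in the colon.

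Mt1 held 31809 counts over the 27 libraries, Mt3 413, Mt4 87 and Mt2 0. Onecut2, a gene of the upper small intestine chosen after its values were seen, held 10.6, 9.51 and 14 CPM in ileum arsenic 12, 14 and 15 and 0.25 to 2.94 CPM in the other ileum libraries.

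The predictions for the splits were written after the counts had been seen. Other splits of the libraries gave at most 253 genes in the ileum against the real 1190. Of 100 splits 1, the real one, was as large, so chance is an unlikely source of this count. The same holds for the cecum (3933 against at most 2399, 1 of 100), cecum against ileum (9266 against at most 0 in edgeR, 1 of 35), colon against cecum (7970 against at most 7328, 1 of 100) and the averaged effect (2878 against at most 201, 1 of 40). In the colon 2 of 100 splits were as large as the real 107, the real one included, so chance is not excluded there. The other 1 gave 238 genes, more than 2 times the real count, with controls 3 and 4 beside arsenic 11 and 13. That split points to a structure of the samples. Of the colon libraries, control 3, control 4 and arsenic 11 had the highest Hox position scores (3.91, 3.31 and 2.01). Arsenic 13 (-1.66) lay just below control 2 (-1.57), and the cause was not tested. For the number of lists chance cannot be excluded: 90 of 100 splits in the ileum were as large (12 real, 28 highest other), 14 of 100 in the cecum (21 and 27), 100 of 100 in the colon (5 and 29), 13 of 35 for cecum against ileum (20 and 25) and 49 of 100 for colon against cecum (19 and 35).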
